A study of Arabidopsis thaliana with 4 samples.

How the data were processed

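Callus was grown from explants of about 1 cm cut from hypocotyls of seedlings kept 9 days in darkness, and was cultured on callus induction medium with 2% sucrose under continuous light at 22 °C for 5 to 6 days, per the labels' protocols. Total RNA was extracted with TRIzol and sequenced on libraries made by standard Illumina protocols. The strand setting of the libraries is not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. The submitters' processing notes name Trim Galore 0.5.0, STAR 2.7.2b, DESeq2 and the genome build TAIR10, without saying what each was used for. The counting tool, the annotation release and the treatment of reads shared by near-identical genes are not given in the sources used here.

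The deposited table holds whole-number read counts per gene for 32833 genes in the 4 libraries, and every value in it is at least 10. The value 10 was held by 33.1% to 35.3% of genes per library, and in wild type replicate 1 the values 10, 11, 12 and 13 were held by 11589, 890, 586 and 387 genes, a decay like that of counts from 0 upward. For genes with a mean deposited value above 10 and up to 20, the variance between libraries of a genotype was 0.413 and 0.422 times the Poisson variance when the values were taken as they are, and 1.68 and 1.70 times after 10 was subtracted. The deposited counts were therefore read as counts to which a constant of 10 had been added, and 10 was subtracted from every value before use. This is an inference from the values. The planned test was on the counts as deposited, and the subtraction, decided after the values were seen, was made because no count model fits a variance below Poisson. The test on unsubtracted values is kept as an alternative. Gene names and positions came from the TAIR10.1 RefSeq annotation, which matched 32548 identifiers. The other 285 are plastid and mitochondrial genes. After the subtraction, 9342 genes had no read in any library.

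Differential expression was computed in R 4.3.3 with edgeR 4.0.16 on all 4 libraries. Genes were kept by filterByExpr (18716 genes), libraries were scaled by TMM, and the mutant was compared with the wild type by glmQLFit and glmQLFTest without covariates, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion corresponds to a biological coefficient of variation of 0.217. Log2 fold changes are the mutant over the wild type, and their SE is the absolute fold change divided by the square root of the quasi-likelihood F. CPM values are TMM-scaled and are given per genotype as mean ± SD (n = 2). Where a genotype held 3 reads or fewer in all, the ratio of read totals is given with an exact (Clopper-Pearson) 95% interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. At these depths 3 reads correspond to 0.0750 to 0.0999 CPM in a library.

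The 18 gene lists (274 tested genes), the rule for named genes, the choice of tests and most alternatives were fixed before the data were examined, but the subtraction of 10, on which the reported values rest, was not. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 lists. Of the 7 lists past the threshold, 0 held with an estimated correlation. That run has only the few degrees of freedom left by 4 libraries, and so little power. A call lost there does not show that correlation between genes made the shift. For the jasmonate and wound list the unadjusted camera p went from 0.00271 to 0.0872, although its estimated correlation (-0.06) lay below the preset value. For all other lists past the threshold the estimate lay above the preset value. It ran from 0.0199 (auxin response and transport) to 0.113 (endodermis and suberin) and 0.517 (xylem and secondary wall). The camera p-values of these lists with the preset value can therefore be too small. With fry, which tests whether the genes of a list move on balance one way and compares them with no other genes, 5 lists passed (auxin synthesis, auxin response and transport, cell cycle, endodermis and suberin, jasmonate and wound). Camera and fry gave opposite directions for the shoot meristem, photosynthesis, hypoxia, and iron and phosphate lists, none of which passed. Named genes were WOX5 and WOX7, the 6 largest rises and 6 largest falls among called genes with a symbol, an average log2 CPM of at least 2 and no overlap between genotypes, the 4 members with the smallest p in each of the root stem cell, auxin synthesis and type-A response regulator lists, and from each other list 2 members where at least 1 passed and otherwise 1. For the neighbourhood of each mutated gene, the 10 tested genes on either side were taken.

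The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (CPM of at least 1), organelle genes left out, DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. Leaving out a library leaves a genotype with 1 library, which is then assumed to vary like the other genotype. For unsubtracted values the dispersion trend was a moving average, because the default local fit failed. DESeq2 with each library left out was added after the data were seen. For the closing section, 20 gene families were formed from product names in the annotation after the results were seen, and their wording was narrowed once when unrelated products were found among the members. Each family was tested for raised and for lowered genes with a two-sided Fisher's exact test against 18326 tested genes with a product name, with adjustment over 40 tests.

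The steps were tested on simulated data for this comparison, with counts drawn for the real genes and 200 genes changed. The changed genes all had an average log2 CPM above 1, and they were fewer than the genes called in the real data. Over 18303 tested genes, 2 of 50 genes changed 1.5-fold were recovered, 18 of 50 changed 2-fold, 43 of 50 changed 4-fold and 49 of 50 changed 8-fold, with no wrong direction. Of the 124 genes called, 12 had not been changed, a share above the nominal threshold. In the list test, 1 of 1 shifted list, with all 20 members raised 2-fold, and 0 of 17 others were called. In the family test 1 of 1 enriched family was called, in which 20 of 60 genes were raised 4-fold or 8-fold, and 0 of 19 others. The other families were drawn without any changed gene, so they could hardly be called and did not test false family calls. Simulated genes varied independently and were put into lists and families at random. False calls from genes that vary together, as real list members can, were therefore not tested.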

Results

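RNA sequencing was performed on callus that formed on hypocotyl explants of Arabidopsis thaliana after culture on callus induction medium, which holds the synthetic auxin 2,4-D at 11 µM and the cytokinin kinetin at 0.2 µM. At the stage labelled as 6 days, where the culture protocol gives 5 to 6 days, the comparison was between the Col-0 wild type and the wox5-1 wox7-1 mutant, which carries mutations in both WOX5 and WOX7. These related genes encode homeobox transcription factors, and WOX5 is best known from the quiescent centre of the root stem cell niche. Each genotype was represented by 2 libraries, and RNA came from about 100 calli. The labels do not say whether the 2 libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries only, which may be technical.

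The wild type libraries held 30041268 and 35975440 gene-assigned reads, and the wox5-1 wox7-1 libraries held 35078420 and 40008661. Reads were found on 21244 to 21959 genes per library. Across genes, log2 CPM (read counts scaled to library size) correlated at 0.978 between the wild type libraries and at 0.970 between the mutant libraries. Between genotypes the 4 correlations lay from 0.925 to 0.954. Genes are not independent replicates, so these correlations only describe the libraries. Within each genotype the libraries differed by more than sampling noise (chi-square per degree of freedom up to 48.6, in the mutant), and all 4 were kept as separate samples. Plastid genes took 0.00181% and 0.00145% of the reads in the wild type and 0.000998% and 0.000775% in the mutant. Mitochondrial genes took 0.00426% and 0.00600% in the wild type and 0.00586% and 0.0105% in the mutant. With 2 libraries against 2, an exact permutation test on both sides of one such share cannot give a p below 0.333.

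WOX5 mRNA was almost lost in the mutant. It stood at 145 ± 1.22 CPM in the wild type and 0.551 ± 0.418 CPM in the mutant (SD, n = 2 each), a log2 fold change of -8.00 (SE 0.42, edgeR adjusted p = 0.00986). The 4 libraries held 4378 and 5268 WOX5 reads in the wild type and 9 and 33 in the mutant, so both libraries labelled as mutant had few. WOX5 (AT3G11260) lies on the plus strand of chromosome 3 from 3527280 to 3528440 in the TAIR10.1 annotation, with 2 exons. WOX7 (AT5G05770) lies on the plus strand of chromosome 5 from 1734427 to 1734855, with 1 exon. Its reads were not lost. They rose from 13.9 ± 1.19 CPM in the wild type to 22.3 ± 0.138 CPM in the mutant (log2 fold change 0.68, SE 0.11, edgeR adjusted p = 0.0335), with 449 and 473 reads against 790 and 864. A count over the whole gene does not tell which part of WOX7 the reads cover, so it does not check that allele. The WOX7 call was lost when any 1 of the 4 libraries was left out, while its log2 fold change lay between 0.59 and 0.77. These fits leave 1 library in a genotype, so a lost call does not show that the rise was absent.

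**Figure D1:**
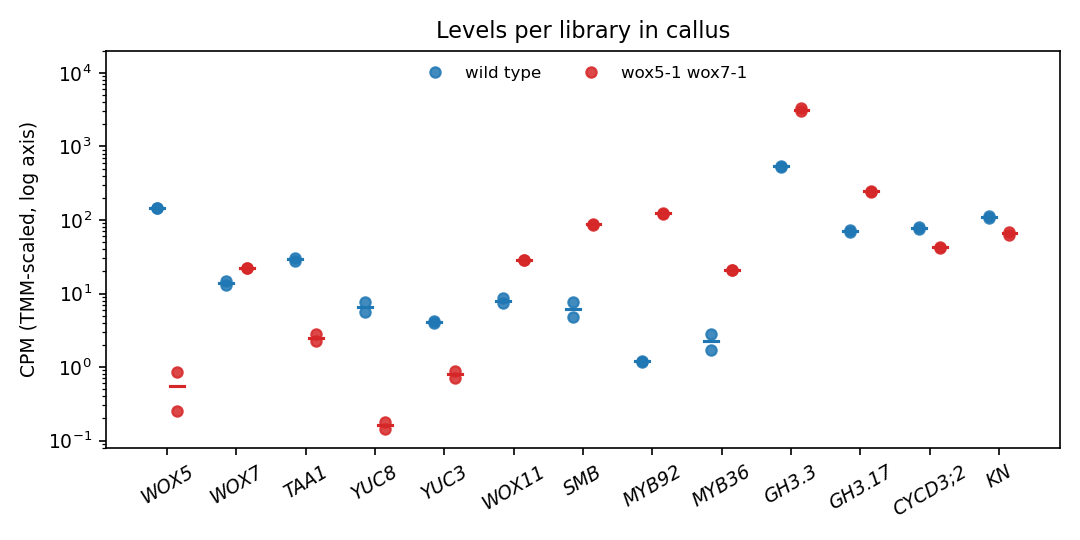
Levels of 13 genes in each of the 4 libraries, in TMM-scaled CPM on a log axis. Points are single libraries (blue, wild type; red, wox5-1 wox7-1), and short bars are genotype means (n = 2). WOX5 fell from 145 to 0.551 CPM and TAA1 from 29.0 to 2.52 CPM, while SMB rose from 6.24 to 87.6 CPM.

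The mutant callus differed from the wild type in 2223 of 18716 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). DESeq2 called 3936, and edgeR with the replicate number as a block called 4750. Of the 2223, 1135 were raised and 1088 were lowered, so 51.1% were raised. At least 2-fold changes were seen in 589 raised and 388 lowered genes, and at least 4-fold changes in 282 raised and 164 lowered genes. All 2223 had both libraries of one genotype above both of the other, as did 12062 of all tested genes (64.4%), where chance gives 33.3%. The count rests on both wild type libraries. Leaving out wild type replicate 1 or 2 left 0 genes past the threshold by edgeR, with 3428 and 3346 at an unadjusted p below 0.05, where DESeq2 called 1334 and 1210, and leaving out mutant replicate 2 left 1198 genes by edgeR. Testing the values as deposited, with the constant of 10 still in them, called 3921 genes, of which 66.5% were raised. That test also covered 32833 genes and used another dispersion trend, so the difference is not that of the constant alone.

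Among called genes with a symbol and an average log2 CPM of at least 2, the largest rises included transcription factors of xylem vessel and suberin programmes. MYB92, which activates suberin genes, rose from 1.22 and 1.19 CPM in the wild type libraries to 121 and 124 CPM in the mutant libraries (log2 fold change 6.67, SE 0.09, edgeR adjusted p = 0.00073). It lies on chromosome 5 from 3232569 to 3234277, and its first exon overlaps the non-coding gene AT5G10278 on the same strand, so reads in the overlap cannot be assigned to one of them with certainty. Of the vessel-related NAC genes, ANAC026 (also called VND5) had 2 reads in the wild type and 590 in the mutant, a ratio of 259 (exact 95% interval 71.5 to 2147, counting error only). NAC105 (also called VND3) rose from 0.107 ± 0.0343 to 10.8 ± 5.96 CPM. EXLB1, an expansin-like gene, rose by a log2 fold change of 5.18 (SE 0.59), MYB305 by 4.72 (SE 0.19) and SGR9, a ubiquitin ligase of gravitropism, by 4.67 (SE 0.23). The same limits leave out genes of lower level and genes without a symbol that fell further, such as AT1G68240 (-6.72, SE 0.32). Under these limits, the largest falls after WOX5 were those of the nitrate transporter gene NRT2:1 (-6.25, SE 0.35), ASL5 (-5.25, SE 0.63), the nuclease gene ENDO3 (-4.33, SE 0.21), the phospholipase gene NPC2 (-4.10, SE 0.25) and MYB34, a regulator of indole glucosinolate synthesis (-3.90, SE 0.42). Their adjusted p-values in edgeR lay between 0.00964 and 0.0230. The calls of NAC105, EXLB1 and ASL5 were lost with limma-voom.

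The auxin synthesis genes TAA1, YUC8 and YUC3 fell. TAA1, whose product converts tryptophan to indole-3-pyruvate, fell from 29.0 ± 2.04 to 2.52 ± 0.396 CPM (SD, n = 2 each; log2 fold change -3.53, SE 0.16, edgeR adjusted p = 0.00964). Of the YUCCA genes, whose products make indole-3-acetic acid from that intermediate, YUC8 fell from 6.55 ± 1.45 to 0.161 ± 0.0269 CPM (-5.32, SE 0.35) and YUC3 from 4.11 ± 0.226 to 0.798 ± 0.113 CPM (-2.36, SE 0.28). Of 8 tested genes in the auxin synthesis list, 3 fell, 0 rose and 5 did not pass the threshold. Adjusted over the list alone, 5 fell and 2 rose. YUC6 had 3 reads in the wild type and 33 in the mutant, a ratio of 9.67 (exact 95% interval 3.03 to 49.3), with an edgeR adjusted p of 0.0589. As a set, the list was lower (median log2 fold change -1.15, camera adjusted p = 0.0358), with adjusted p = 0.0237 by fry and 0.556 with an estimated correlation. The set call was also lost without wild type replicate 1 (0.102), wild type replicate 2 (0.0673) or mutant replicate 1 (0.429), and with all libraries when no low-count filter was used (0.0513).

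Genes of the root stem cell niche and of callus founder cells moved in both directions. Of 24 tested, 9 fell, 5 rose and 10 did not pass the threshold, and adjusted over the list alone 11 fell and 7 rose. The list did not shift as a set (camera adjusted p = 0.489). SMB, a regulator of root cap maturation, rose from 6.24 ± 2.14 to 87.6 ± 2.53 CPM (SD, n = 2 each; log2 fold change 3.82, SE 0.26). WOX11, a regulator of founder cells in adventitious rooting, rose from 8.65 and 7.36 CPM to 28.4 and 28.8 CPM (1.84, SE 0.12), and the lateral organ boundaries gene LBD17 rose by 1.93 (SE 0.14). After WOX5, the largest falls past the threshold in this list were those of NUC, with 328 reads in the wild type and 2 in the mutant, a wild type to mutant ratio of 187 (exact 95% interval 51.2 to 1547), and RGF3, with 116 reads and 1 read (ratio 132, interval 23.2 to 5256). JKD and SCR, transcription factor genes of the root ground tissue, fell by 1.45 (SE 0.12) and 0.73 (SE 0.08) on the log2 scale, and the embryogenic regulator BBM fell by 0.65 (SE 0.08). These 5 genes were chosen after their values were seen, and their edgeR adjusted p-values lay between 0.0161 and 0.0263.

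None of the 7 tested type-A response regulators, which dampen cytokinin signalling, passed the threshold over all genes by edgeR. All 7 had a positive fold change, and adjusted over the list alone 5 rose. ARR4 had 160 ± 4.36 CPM in the wild type and 202 ± 3.19 in the mutant (log2 fold change 0.34, SE 0.07, edgeR adjusted p = 0.0514). ARR6 had a log2 fold change of 1.57 (SE 0.33, adjusted p = 0.0526), ARR7 of 1.94 (SE 0.54, adjusted p = 0.0862) and ARR5 of 0.77 (SE 0.22, adjusted p = 0.0913). By DESeq2 all 4 passed the threshold, and ARR4 and ARR6 also passed it by edgeR with the stricter filter. As a set they were higher (median 0.71, camera adjusted p = 0.00665), with adjusted p = 0.464 with an estimated correlation and 0.0647 by fry. Of 23 other cytokinin genes, 2 rose and 2 fell (camera adjusted p = 0.850), and adjusted over the list alone 2 rose and 4 fell. CKX3, which encodes a cytokinin-degrading oxidase, rose by 0.71 (SE 0.08), and the receptor gene AHK2 fell by 0.58 (SE 0.09). The median of this list was -0.003 and its mean 0.007, and the median changed sign with the scaling.

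Of 40 tested auxin response and transport genes, 30 had a positive fold change. Past the threshold, 9 rose, 5 fell and 26 did not pass the threshold, and adjusted over the list alone 19 rose and 6 fell. GH3.3, whose product conjugates auxin to amino acids, rose from 534 ± 4.43 to 3157 ± 223 CPM (SD, n = 2 each; log2 fold change 2.56, SE 0.11, edgeR adjusted p = 0.00964). GH3.17, of the same family, rose from 70.6 ± 3.55 to 245 ± 8.22 CPM (1.79, SE 0.08). Chosen after its value was seen, the influx carrier gene LAX2 fell by 1.90 on the log2 scale (SE 0.10). The set was higher (median 0.37, camera adjusted p = 0.00256), with adjusted p = 0.0274 by fry and 0.464 with an estimated correlation.

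Of 20 tested endodermis and suberin genes, 10 rose, 0 fell past the threshold and 10 did not pass it, and adjusted over the list alone 14 rose and 1 fell (edgeR; 16 members had a positive and 4 a negative fold change). Besides MYB92, MYB36, a regulator of Casparian strip formation, rose from 2.24 ± 0.783 to 20.9 ± 0.0445 CPM (SD, n = 2 each; log2 fold change 3.23, SE 0.27). The set was higher, with a median of 1.98 (camera adjusted p = 8.16e-06, adjusted p = 0.0237 by fry and 0.464 with an estimated correlation). Xylem and secondary wall genes were also higher as a set (median 1.58, camera adjusted p = 0.00256), with adjusted p = 0.788 with an estimated correlation and 0.183 by fry. Of 13 tested, 2 rose and 11 did not pass the threshold, and 5 rose when adjusted over the list alone. The 2 were XCP1, a protease gene of xylem vessels (0.467 ± 0.269 to 4.91 ± 1.46 CPM), and the laccase gene LAC4 (log2 fold change 2.67, SE 0.49), whose call was lost with limma-voom.

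Cell cycle genes were lower. Of 29 tested, 14 fell, 0 rose and 15 did not pass the threshold, and adjusted over the list alone 19 fell and 4 rose. CYCD3;2, a D-type cyclin gene, fell from 77.9 ± 3.97 to 42.4 ± 1.42 CPM (SD, n = 2 each; log2 fold change -0.88, SE 0.08), and KN, a cytokinesis syntaxin gene, fell from 110 ± 4.76 to 65.6 ± 4.29 CPM (-0.75, SE 0.08). The set median was -0.43 (camera adjusted p = 0.000696), with adjusted p = 0.0274 by fry and 0.464 with an estimated correlation.

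**Figure D2:**
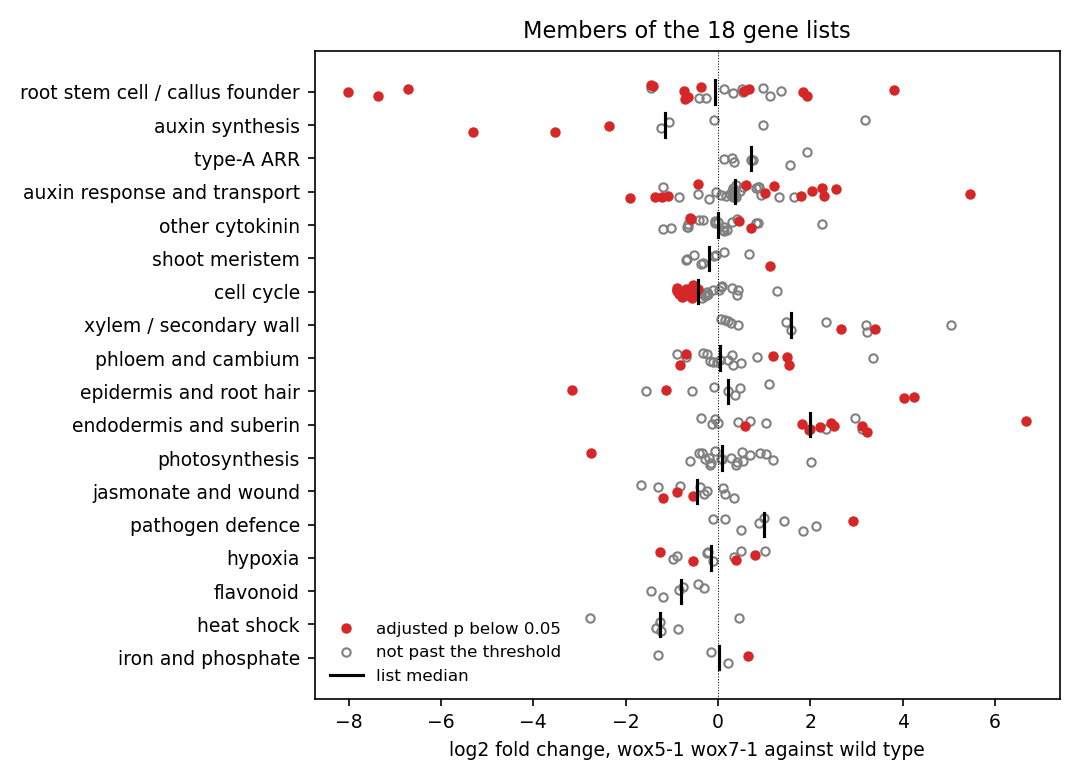
Log2 fold change of the tested members of the 18 gene lists, wox5-1 wox7-1 against wild type (2 libraries each). Each point is a gene (filled, edgeR adjusted p below 0.05; open, not past that threshold) and black bars are list medians. The endodermis and suberin median lay at 1.98 and the cell cycle median at -0.43.

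The jasmonate and wound list was lower (median -0.46, camera adjusted p = 0.00813), with adjusted p = 0.0237 by fry, 0.464 with an estimated correlation and 0.0677 by camera without a low-count filter. Of 12 tested, 3 fell and 9 did not pass the threshold, and 6 fell when adjusted over the list alone. WIND2, from a family of wound-induced dedifferentiation factors, fell from 82.6 ± 1.37 to 35.9 ± 1.77 CPM (SD, n = 2 each), and AOS, which encodes a jasmonate synthesis enzyme, fell by 0.88 on the log2 scale (SE 0.11).

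Lists for other cell types did not shift as sets. Of 19 phloem and cambium genes, 3 rose and 2 fell (camera adjusted p = 0.609; 4 rose and 2 fell adjusted over the list alone). OPS, a regulator of phloem differentiation, rose from 32.5 ± 0.676 to 91.9 ± 19.7 CPM, and SMXL3 fell by 0.83 on the log2 scale (SE 0.10). Of 11 epidermis and root hair genes, 2 rose and 2 fell (camera adjusted p = 0.523; 4 and 4 adjusted over the list alone). The root hair regulator RHD6 rose by 4.24 (SE 0.36), and PDF2 (AT4G04890), which maintains epidermal identity, fell by 1.13 (SE 0.19). Of 21 photosynthesis genes, 1 fell, GLK2, a regulator of chloroplast development (-2.76, SE 0.36; camera adjusted p = 0.789; 1 fell adjusted over the list alone). HEMA1 had a log2 fold change of 0.39 (SE 0.11, edgeR adjusted p = 0.0821). Without mutant replicate 2 the photosynthesis list passed (camera adjusted p = 0.0287). Of 10 shoot meristem genes, 1 rose, the ethylene response factor gene RAP2.6L (1.14, SE 0.07; camera adjusted p = 0.789; 1 rose adjusted over the list alone), and KNAT6 had a log2 fold change of 0.66 (SE 0.16, edgeR adjusted p = 0.0672).

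Stress and nutrient lists varied between libraries. Of 9 pathogen defence genes, 1 rose, PAD4, from 26.5 ± 14.5 to 202 ± 114 CPM (SD, n = 2 each; log2 fold change 2.93, SE 0.60, edgeR adjusted p = 0.0497), and 2 rose adjusted over the list alone. The PAD4 call was lost with RLE scaling (0.0501) and limma-voom. ICS1, a salicylic acid synthesis gene, had a log2 fold change of 2.12 (SE 0.48, adjusted p = 0.0599). Against the wild type mean, the list median was 0.25 in mutant replicate 1 and 1.52 in mutant replicate 2, and the set missed the threshold (camera adjusted p = 0.0501), passing it without wild type replicate 1 (0.0120) or mutant replicate 1 (0.00253). With all libraries it also passed with upper-quartile scaling (0.0392), the replicate number as a block (0.0418), the stricter filter (0.0489), no filter (0.00898) and the values as deposited (0.00114), so its side of the threshold is not settled. None of 6 flavonoid genes passed by edgeR or adjusted over the list alone (camera adjusted p = 0.136). Their median was -0.26 in mutant replicate 1 and -1.80 in mutant replicate 2. The flavonoid set passed with the replicate number as a block (camera adjusted p = 0.0351), and also without mutant replicate 1. CHI (AT3G55120), a flavonoid synthesis gene, had a log2 fold change of -0.85 (SE 0.33, edgeR adjusted p = 0.154). None of 6 heat shock genes passed by edgeR or adjusted over the list alone (camera adjusted p = 0.420). Their median was -0.69 and 0.69 in the wild type libraries and -1.22 and -0.69 in the mutant libraries, and the set passed without wild type replicate 1 (0.000473). HSFA2, a heat shock factor gene, had a log2 fold change of -1.25 (SE 0.33, edgeR adjusted p = 0.0776). Of 12 hypoxia genes, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.850). The fermentation genes ADH1 and PDC1 changed by 0.80 (SE 0.08) and -1.25 (SE 0.23). Of 4 iron and phosphate genes, 1 rose, the ferritin gene FER1 (0.65, SE 0.13), while SPX1 had a log2 fold change of -1.30 (SE 0.34, edgeR adjusted p = 0.0765). Adjusted over the list alone 1 rose and 1 fell, the list median was 0.03 and its mean -0.15 (camera adjusted p = 0.878), and the FER1 call was lost with upper-quartile scaling (0.0526) and limma-voom.

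Genes beside both loci were also measured. Of the 20 nearest tested genes around WOX5, 4 rose and 0 fell (edgeR), with a median log2 fold change of 0.30. Among all tested genes with a product name, 6.12% rose. The 4 were the neighbours directly before WOX5, AT3G11250 (0.49, SE 0.07), ATE2 (0.85, SE 0.14) and AT3G11230 (0.71, SE 0.14), and UGT76B1 after it (2.64, SE 0.41). They were named after their values were seen, and an effect of the WOX5 allele on them was not tested. Of the 20 around WOX7, 2 rose and 0 fell, with a median of 0.05. The 2 were SYP31, directly before WOX7 (0.88, SE 0.09), and ATL43 (0.57, SE 0.11), both named after their values were seen.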

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

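The values as deposited were the planned unit, while the subtraction of 10 and the DESeq2 fits with a library left out were chosen after the data were seen. RLE and upper-quartile factors, no filter, the stricter filter and leaving out organelle genes gave 2090 to 2615 changed genes, and limma-voom gave 1698. DESeq2 called 3936 genes (2180 raised, 1756 lowered), 2217 of them among the 2223. The values as deposited gave 3921 (2609 raised), 2060 of them among the 2223. The causes of these differences were not tested. With a library left out, edgeR called 0, 0, 2493 and 1198 genes (0 to 1452 raised, 0 to 1041 lowered; 651 and 547 without mutant replicate 2), and DESeq2 called 1334, 1210, 3055 and 2045 (1735 raised without mutant replicate 1; 493 and 417 lowered without a wild type library). WOX5 then ranged from -9.13 to -7.41 (adjusted p up to 0.103) and WOX7 from 0.59 to 0.77 (adjusted p up to 0.220). With an estimated correlation, a run with little power at 4 libraries, 0 of the 7 list calls held. Of 40 called named genes, 6 lost the call in a setting with all libraries (NAC105, EXLB1, ASL5, LAC4, PAD4 and FER1) and 0 changed sign, while all 11 uncalled named genes passed in at least 1 such setting. The labels do not say whether same-numbered libraries share more than a number. With the replicate number as a block, 4750 genes were called (2527 raised, 2223 lowered), among them 10 of the 11 uncalled named genes. The pathogen defence and flavonoid lists then also passed (camera adjusted p = 0.0418 and 0.0351). The differences between replicates correlated between genotypes at 0.555 over 18716 genes, at 0.554 after thinning to equal totals and at 0.244 without the 1000 most variable genes. With 2 pairs, a shared day cannot be told from chance.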

Other observations

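Product families were formed, and their tests chosen, only after the results were seen, as were the tests on WOX7, on other groupings of the libraries and on other differentiated cell types. Kinesin and histone genes fell more often than the other tested genes. Of 42 tested genes for kinesins and other microtubule motors, 19 fell and 0 rose (odds ratio 13.4, Fisher's exact adjusted p = 1.8e-11), where 5.88% of all tested genes with a product name fell. Among them were POK1 (88.3 to 44.0 CPM), which orients the phragmoplast, HIK (log2 fold change -0.65, SE 0.09) and ATK1 (-0.70, SE 0.09). Of 43 histone genes, 11 fell and 0 rose (odds ratio 5.55, Fisher's exact adjusted p = 0.000186), including HTB1 (-0.82, SE 0.14). Of 16 xyloglucan endotransglucosylase genes, whose products remodel the cell wall, 5 fell and 1 rose (adjusted p = 0.00656 for falls). XTH9 fell from 106 to 18.3 CPM, while XTH11 rose by 3.91 on the log2 scale (SE 0.22). Of 42 GDSL lipase genes, 8 fell and 4 rose (adjusted p = 0.00847 for falls). Against the wild type mean, the GDSL lipase median was -0.478 in mutant replicate 1 and -0.0925 in mutant replicate 2, where the wild type libraries lay at -0.0945 and 0.0945. In the same mutant libraries the medians were -0.447 and -0.246 for xyloglucan endotransglucosylase, -0.549 and -0.391 for histone, and -0.368 and -0.499 for kinesin and motor genes. Ribosomal protein genes were called less often than others, with 3 of 298 raised (adjusted p = 0.000145) and 6 lowered (adjusted p = 0.00656). Genes of a family are not independent, so these p-values are too small.

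Several families held more raised genes than the background. Of 65 MYB domain genes, 17 rose and 3 fell (odds ratio 5.50, Fisher's exact adjusted p = 4.8e-06). Besides MYB92 and MYB36 they included MYB107 (log2 fold change 3.42, SE 0.32), a regulator of suberin in seed coats. Of 64 NAC domain genes, 10 rose and 2 fell (adjusted p = 0.0150 for rises), among them NAC075 (1.34 to 25.6 CPM). Of 34 lipid transfer or 2S albumin genes, 10 rose and 1 fell (odds ratio 6.44, adjusted p = 0.000186), among them LTP5 (1.09 to 26.6 CPM). Of 75 genes for TIR-NBS-LRR immune receptors, 16 rose and 2 fell (adjusted p = 0.00013). SNC1 rose from 6.51 to 48.2 CPM and RPP4 from 0.575 to 5.54 CPM. Their near-identical neighbours can share reads, so single members are uncertain. Rises also exceeded the background in 115 cytochrome P450 genes (17 rose and 8 fell, adjusted p = 0.00355), 24 MtN21-type transporter genes (6 rose and 0 fell, adjusted p = 0.00847), 42 late embryogenesis abundant genes (7 rose and 4 fell, adjusted p = 0.0325) and 45 class III peroxidase genes (9 rose and 3 fell, adjusted p = 0.00656). Basic helix-loop-helix genes went both ways, with 13 of 83 raised (adjusted p = 0.00656) and 10 lowered (adjusted p = 0.0665). Against the wild type mean, the medians were lower in mutant replicate 1 than in mutant replicate 2 for peroxidase (-0.06 and 1.90), lipid transfer (0.436 and 1.197), late embryogenesis abundant (0.0713 and 0.547), MtN21-type (0.161 and 0.502), NAC (0.243 and 0.589), cytochrome P450 (0.114 and 0.269), TIR-NBS-LRR (0.513 and 0.783) and basic helix-loop-helix genes (0.188 and 0.250), and nearly even for MYB genes (0.440 and 0.418). Of 117 heat shock or DnaJ genes, 1 rose (adjusted p = 0.0277 for fewer rises). Expansin, pectin lyase-like, UDP-glucosyltransferase, SAUR-like and AP2/ERF genes passed in neither direction. The AP2/ERF wording matched only 11 tested genes and missed the raised ethylene response factor gene RAP2.6L, so it gives no result for that family. These counts rest on the calls from all 4 libraries, and no gene was called by edgeR when a wild type library was left out.

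The 4 libraries can be split 2 against 2 in 3 ways. The genotype split called 2223 genes and the highest of the other splits called 0 by edgeR (at an unadjusted p below 0.05, 642 genes by replicate number and 19 in the crossed split), so 1 of 3 splits reached the real count. With 3 splits no share under 0.05 can be had. Each of the other splits also puts 1 library of each genotype in both groups. Differences between genotypes then count as spread within groups, so these splits could hardly reach the real count and tested little.

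WOX7 reads were higher in the mutant although WOX7 is one of the mutated genes. Reads of WOX5 counted as WOX7 would be lost with WOX5 and lower WOX7, so they cannot account for a rise (log2 fold change 0.68, SE 0.11), and this value was no separate test. A rise of the whole neighbourhood is argued against by the 20 nearest tested genes, whose median was 0.0529 (median absolute deviation 0.28), although SYP31 directly before WOX7 rose by 0.88. The WOX7 rise itself lost its call with any 1 library left out, in fits with 1 library in a genotype. Its log2 fold change then lay between 0.59 and 0.77. Transcripts that start or end in the altered allele may be the source of the reads, and a response of the locus to the loss of WOX5 is another candidate explanation. Coverage along the gene, not analysed here, would separate them.

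Of 20 tested endodermis and suberin genes 10 rose, and of 29 cell cycle genes 14 fell. The first list, called suberin below, also holds Casparian strip genes such as MYB36. Both sets passed by fry (adjusted p = 0.0237 and 0.0274). Neither passed with an estimated correlation (camera adjusted p = 0.464 for each), a run with little power at 4 libraries. A gain of all other differentiated cell types by the same factor would raise their markers alike. The suberin median exceeded that of photosynthesis and phloem genes by 1.91, a contrast of medians already seen. Against the wild type mean, the suberin median was 1.72 and 1.89 in the mutant libraries. The photosynthesis median was 0.43 and -0.29 there, and 0.29 and -0.29 in the wild type libraries. These values argue against such an equal gain only, and gains that differ between cell types stay open. Xylem genes, left out of that contrast, had a median of 1.58 with 2 of 13 past the threshold (camera adjusted p = 0.788 with an estimated correlation, 0.183 by fry). GC content and gene length are argued against as the whole cause, since after a loess correction the suberin median was 1.95 and the cell cycle median had an absolute value of 0.491. The 4 scalings moved the median of all genes only between -0.03 and 0.01 and so tested little (cell cycle median nearest to 0, -0.43; lowest suberin median, 1.96), but a scaling factor moves all genes of a library alike and cannot by itself raise one list and lower the other. A hypothesis that stays open is that more cells of the mutant callus take a suberised or vessel fate and fewer divide, where counts of such cells in the calli, not analysed here, would decide between a changed share of cells and changed expression within cells, and a difference in culture stage was not tested.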
